A study of Homo sapiens with 12 samples.

How the data were processed

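RNA from 12 libraries, 4 each of HUVEC, CASMC and iEC, was polyA-selected and sequenced in paired reads of 100 bases, per the labels' protocols. The authors deposited 1 table of whole-number read counts per gene symbol for all 12 libraries. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.2b and featureCounts of Subread 1.5.2 were used, with the builds GRCh38 and GRCm38. The strand setting and annotation release are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The table held 15902 genes, each with at least 10 reads in at least 5 libraries. All symbols matched a gene of GENCODE 29 (GRCh38), 34 of them at more than 1 locus, and coordinates are from that annotation.

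Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R. The function filterByExpr removed 27 genes and left 15875. Counts were scaled by TMM, and glmQLFit and glmQLFTest were run with 1 mean per group and no covariate, so that the 3 groups shared 1 estimate of the spread (9 residual degrees of freedom). Genes were called at a Benjamini-Hochberg adjusted p under 0.05. CPM used TMM-scaled library sizes, and log2 CPM had a prior count of 1. A fold against a group with no reads is a lower bound against a floor of 3 counts per library. Such floors cover counting error only, and total counts of 16102667 to 30849935 set them between 0.0893 and 0.171 CPM.

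Before the data were examined, 28 gene lists with 727 entries were fixed, of which 621 were measured, together with the comparisons, the alternatives and the rule for named genes. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists of a comparison, and counts of called members are given over all genes and adjusted over the list alone. Genes were named for iEC against CASMC and against HUVEC as the 10 highest and 10 lowest fold changes with an adjusted p under 0.05, an average log2 CPM of at least 4, no overlap between the libraries of both groups and a protein-coding symbol that is not a clone or locus name. The number was 5 each for HUVEC against CASMC. The rule also took the extreme members of each list and 18 genes named in advance. The text leaves out some of these. The iEC libraries hold 2 mimics and 2 inhibitors, and 3′ UTR matches were searched in 12632 genes.

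On 5 simulated data sets of iEC against CASMC with 200 changed genes, run on about 14806 genes, the test recovered 1.14% of genes changed by 0.5 on the log2 scale, 33.4% of those changed by 1 and 84.0% of those changed by 2. False calls made up 4.22% of the calls. A list shifted by 1 was found in 5 of 5 simulated sets, with 0 calls of other lists. Simulated genes were independent, unlike real ones.

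Alternatives were size factors of DESeq2 1.42.0, upper-quartile scaling, the DESeq2 Wald test, other filters, fits of the 2 groups alone, stricter thresholds, a fit with the replicate number, each library left out, and estimated correlations and fry for the lists. Replicates were checked for duplicate deposits: the lowest chi-square per degree of freedom between 2 libraries of a group was 15.7, so no pair agreed within sampling noise. The cutoffs of the check for mixed-up samples, which compared iEC with CASMC libraries, were set after its values were seen. The count of iEC libraries that did not match was 4 at each of 4 cutoffs.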

Results

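Polyadenylated RNA was sequenced from 12 libraries of human cells, 4 in each of 3 groups. HUVEC are primary endothelial cells of the umbilical vein, and CASMC are primary smooth muscle cells of the coronary artery. By its labels, the iEC group is CASMC transfected with mimics of miR-146a-5p and miR-181b-5p together with inhibitors of miR-143-3p and miR-145-5p, used at 50 nM. A mimic is a synthetic copy of a microRNA, and an inhibitor is an oligonucleotide that blocks one. HUVEC and iEC were kept in endothelial medium and CASMC in smooth muscle medium, so transfection and medium changed together between CASMC and iEC. Total counts of replicates 1 to 4 were 16102667, 21878501, 30849935 and 29568541 in HUVEC, 21201091, 24372577, 24967155 and 23377826 in CASMC, and 19408766, 29739255, 22031999 and 26578667 in iEC. The labels number the samples of a group but do not say that they came from separate cultures or donors, so the p-values measure the spread between these samples, which may be technical.

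In a check for mixed-up samples, which compared only the iEC with the CASMC libraries, none of the 4 iEC libraries matched the CASMC sequenced. The check does not say whether iEC came from other CASMC or from another kind of cell. Differences between iEC and CASMC therefore cannot be told apart from differences between cell sources. All genes in the deposited table had at least 10 reads in at least 5 libraries, so a gene expressed in a single group of 4 is missing from it.

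The groups separated on the first principal component, which held 58.1% of the variance of log2 CPM (counts scaled to library size), with iEC on the HUVEC side. On the second (18.9%), iEC replicates 1 to 3 lay at -107.3 to -90.8 and replicate 4 at -18.8. HUVEC lay there at 54.6 to 71.5 and CASMC at 12.5 to 18.3. Across genes, which are not independent replicates, the median Spearman correlation was 0.917 between iEC and HUVEC libraries, 0.848 between iEC and CASMC, and 0.828 between HUVEC and CASMC. iEC replicate 4 correlated with the HUVEC libraries at a median of 0.950, against 0.905 to 0.916 for the other 3 iEC libraries. Mitochondrially encoded transcripts took 5.64% ± 1.06 (SD, n = 4) of counts in iEC, 4.08% ± 0.474 in CASMC and 3.44% ± 0.133 in HUVEC. The share was higher in iEC than in HUVEC (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 can give), while iEC against CASMC gave an exact p of 0.0571.

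**Figure D1:**
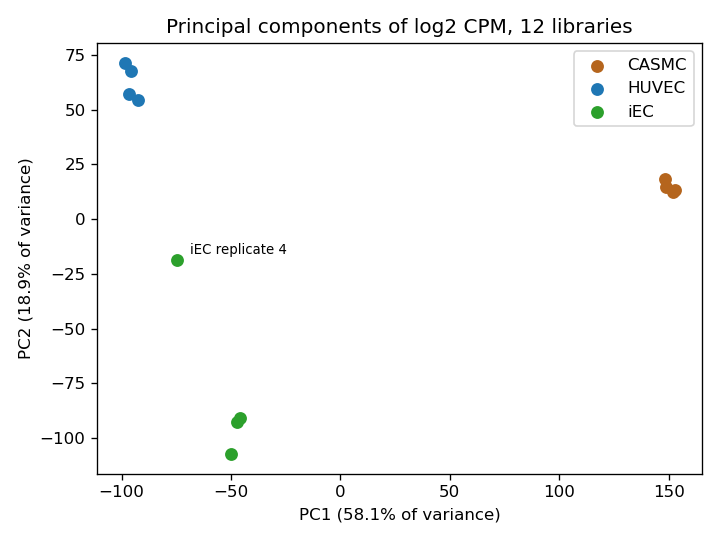
Principal components of log2 CPM, with 1 point per library coloured by group and both axes in component scores. CASMC lie on the right, at 148.5 or more on the first component, and iEC replicate 4 lies between HUVEC and the other 3 iEC libraries.

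The comparison of iEC with CASMC asks how the cells labelled as CASMC given the 4 agents and the endothelial medium differed from the CASMC sequenced. PECAM1 and CDH5 were high in iEC and low in CASMC. PECAM1, an adhesion molecule of endothelial junctions (chromosome 17, 64319415 to 64413776, minus strand, GRCh38), stood at 2567 ± 720 CPM in iEC against 3.16 ± 1.20 in CASMC (SD, n = 4 each). CDH5, the cadherin of endothelial junctions (chromosome 16, 66366622 to 66404786, plus strand), stood at 1299 ± 118 against 3.31 ± 0.909 CPM. ENG, a TGF-beta co-receptor of endothelial cells, was abundant in both, at 1525 ± 192 CPM in iEC and 594 ± 70.9 in CASMC. The fibrillar collagens COL1A1 and COL3A1 were lower in iEC: COL1A1 (chromosome 17, 50183289 to 50201632, minus strand) was at 3.65 ± 0.557 CPM in iEC and 10640 ± 1975 CPM in CASMC, and COL3A1 at 4.394 ± 1.501 against 7611 ± 1115 CPM. COL4A1, a collagen of basement membranes, was higher in iEC, at 1817 ± 282 against 81.1 ± 12 CPM.

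Of 15875 genes tested, 3162 were higher and 2557 lower in iEC (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), of which 2135 and 1579 differed by at least 2-fold. Of the 44 measured endothelial surface, junction and effector genes, 42 were higher in iEC and 1 was lower, with a median log2 fold change of 6.02, or 5.29 with genes at 0 in CASMC set to their lower bound. The counts were 42 and 1 adjusted over the list alone, and the list's camera adjusted p was 6.22e-82, or 2.28e-06 with an estimated correlation. The scavenger receptor STAB1 had a log2 fold change of 10.54 ± 0.28 (SE), and the von Willebrand factor gene VWF 8.01 ± 0.79 (9.03 without CASMC replicate 1 and 7.31 without iEC replicate 4). NOS3, which encodes endothelial nitric oxide synthase, had 4.30 ± 0.37, and the angiopoietin receptor TEK 3.18 ± 0.37. ARHGEF15 had no reads in CASMC and was at least 295-fold higher in iEC, against a floor of 3 counts per library. The lower gene was TFPI2, at a log2 fold change of -4.79. Among 27 endothelial transcription factors 17 were higher and 2 lower (18 and 3 adjusted over the list alone; camera adjusted p = 1.52e-07, and 0.0271 with an estimated correlation), with ERG at 8.31 ± 0.54 (9.56 without CASMC replicate 1).

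Of 34 genes of fibrillar and mesenchymal matrix, 30 were lower in iEC and 1 was higher, with a median log2 fold change of -4.17 (30 and 1 adjusted over the list alone; camera adjusted p = 7.41e-36, and 0.00589 with an estimated correlation). Secreted and matrix genes among those with the lowest fold changes included SFRP4 (-11.38 ± 0.51), a secreted Wnt-binding protein, THBS2 (-10.62 ± 0.45) and COL6A3 (-10.01 ± 0.40). Smooth muscle contractile genes and regulators moved in both directions: of 32 measured, 16 were lower and 5 higher (the same counts adjusted over the list alone), with a camera adjusted p of 0.0151. With an estimated correlation the adjusted p was 0.264. ACTA2, smooth muscle actin, had a log2 fold change of -4.22 ± 0.28, TAGLN -1.94 ± 0.33 and CNN1 -2.60 ± 0.54, while FHL1 was higher at 2.09 ± 0.25. MYOCD had -3.73 ± 0.90 on 12 reads in iEC, 10 of them in 1 library, and -5.82 without iEC replicate 3. MYH11, the smooth muscle myosin heavy chain, did not pass the test (-0.61 ± 0.50, adjusted p = 0.372, and -1.23 with 0.0704 without iEC replicate 3) and stood near 1.00 CPM in CASMC. KLF4 is not in the smooth muscle list but in those of endothelial transcription factors, pluripotency genes and reported miR-143-3p and miR-145-5p targets. KLF4 passed at an adjusted p of 0.0448 (-1.16 ± 0.42) and lost the call when any 1 of the CASMC libraries or iEC replicate 1, 2 or 3 was left out, with adjusted p-values of 0.0514 to 0.124, the last without iEC replicate 2. Over all alternatives its adjusted p ran from 0.00666 to 0.124.

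Interferon response genes were higher in iEC in 28 of 35 cases and lower in 0, with a median of 3.22 (30 and 0 adjusted over the list alone; camera adjusted p = 6.54e-11). With an estimated correlation the adjusted p was 0.264. Of 24 genes of the sterol synthesis list, 16 were lower and 0 higher (17 and 0 adjusted over the list alone; camera adjusted p = 8.71e-05, and p = 0.264 with an estimated correlation), with HMGCS1 at -1.98 ± 0.29. Of 30 genes of hypoxia and glycolysis, 17 were lower and 1 higher (18 and 1 adjusted over the list alone; camera adjusted p = 2.25e-05, and p = 0.264 with an estimated correlation). Without iEC replicate 4, whose mean over this list was 7.65 log2 CPM against 6.31 to 6.43 in the other 3 iEC libraries, 24 were lower. Of 40 cell cycle genes, edgeR called 0 with all libraries (0 at an unadjusted p under 0.05, and 0 called by DESeq2). Without iEC replicate 4, 20 were lower, and the camera adjusted p of the list went from 0.0826 to 0.000204. With an estimated correlation and all libraries the adjusted p was 0.824.

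None of the 3 lists of reported targets of the 4 microRNAs passed camera. For the reported miR-146a-5p targets 6 of 18 were higher and 3 lower (camera adjusted p = 0.330), and for those of miR-181b-5p 6 of 17 and 3 (adjusted p = 0.731). For those of miR-143-3p and miR-145-5p 16 of 34 were higher and 14 lower (adjusted p = 0.802). For these 3 lists the counts were the same adjusted over the list alone. The medians of the last 2 lists were 0.34 and 0.35 while their means were -0.19 and -0.24, so that median and mean differed in sign. Of 3 reported targets of miR-146a-5p and miR-181b-5p in NF-kappaB signalling, IRAK1 had a log2 fold change of 0.38 ± 0.20 (adjusted p = 0.155) and KPNA4 0.20 ± 0.20 (adjusted p = 0.480). TRAF6 had 0.79 ± 0.26 (adjusted p = 0.0277) and lost its call when CASMC replicate 1, 3 or 4 or iEC replicate 2 or 3 was left out, with adjusted p-values of 0.0501 to 0.0762, the last without CASMC replicate 1. Over all alternatives its adjusted p ran from 0.0103 to 0.0762. CARMN, the transcript that hosts miR-143 and miR-145, was lower in iEC (-5.10 ± 0.85) on 29 reads there, 21 of them in 1 library, and had -6.64 without iEC replicate 3. MIR3142HG, which hosts miR-146a, was higher (4.85 ± 0.90, and 5.68 without CASMC replicate 3). Of the hosts of miR-181 genes, MIR181A2HG did not pass (-0.28 ± 0.50, adjusted p = 0.706). MIR181A1HG passed at an adjusted p of 0.0457 (1.07 ± 0.39) and lost the call without HUVEC replicate 2, CASMC replicate 1, 2 or 3, or iEC replicate 1, 2 or 4, with upper-quartile scaling and with the libraries of both groups alone. Over all alternatives its adjusted p ran from 0.0193 to 0.126.

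Genes with a match to positions 2 to 8 of a microRNA in the longest 3′ UTR were set against genes with none. The median log2 fold change of the 1666 genes with a miR-146a-5p site was 0.010, against 0.063 without. This lay at the 30.3 percentile of 1000 random 7-mers (946 for miR-181b-5p), and at the 62.2 percentile in HUVEC against CASMC, where no mimic was used. The percentiles for miR-181b-5p, miR-143-3p and miR-145-5p were 42.5, 82.8 and 90.3 in iEC against CASMC, and 94.8, 50.3 and 81.4 in HUVEC against CASMC. None of the 4 sets passed camera in iEC against CASMC (adjusted p = 0.878 for each).

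The comparison of HUVEC with CASMC gives the difference between the endothelial and smooth muscle references. In HUVEC 3471 genes were higher and 3200 lower. CLDN5, a claudin of endothelial tight junctions, had a log2 fold change of 11.13 ± 0.45, and VWF 10.51 ± 0.85 (11.82 and 11.54 without CASMC replicate 1). SFRP4 had -11.27 ± 0.50, at 0.733 CPM in HUVEC and 1699 CPM in CASMC. The endothelial surface list had 42 of 44 members higher and 1 lower (the same adjusted over the list alone; camera adjusted p = 7.55e-70), and the matrix list 31 of 34 lower and 2 higher (the same adjusted over the list alone, and 1 higher with DESeq2; camera adjusted p = 4.45e-39). Without HUVEC replicate 2 the matrix list had 0 higher. Both lists held with an estimated correlation (adjusted p = 2.33e-06 and 0.000740). In both comparisons against CASMC the 6 lists that held with it were endothelial surface genes, endothelial transcription factors, matrix, mesenchymal transition factors, lymphatic endothelial genes and Notch signalling. In iEC against HUVEC the 3 were NF-kappaB, TGF-beta and angiogenic genes. NF-kappaB inflammatory genes were lower in HUVEC in 24 of 33 cases and higher in 3 (the same adjusted over the list alone; camera adjusted p = 6.06e-13, and p = 0.0783 with an estimated correlation). Cell cycle genes were higher in 16 of 40 cases (the same adjusted over the list alone; camera adjusted p = 0.0223, and p = 0.764 with an estimated correlation). The count was 4 without HUVEC replicate 4, when the camera adjusted p was 0.151, and 33 without iEC replicate 4.

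Calls against the shared CASMC libraries overlapped. 2101 genes were higher in both iEC and HUVEC, where 691 would be shared by independent lists, and 1751 were lower in both, against 515. The deposited table lacks genes expressed in a single group, so a gene nearly absent from CASMC needs reads in both other groups. This can raise the shared higher calls, so 691 and 515 are not fair expectations. The filter bears on the correlation and the slope as well. Simulated unchanged groups with the same controls gave 0 shared calls in either direction. With no gene changed few calls can arise, so this gives no expected overlap for groups that both differ from CASMC. With the CASMC libraries split between the 2 comparisons, 1445 to 1500 genes were higher and 1244 to 1302 lower in both. The correlation of the fold changes across genes was 0.810 (0.750 to 0.764 with split controls), against a simulated 0.508, and their covariance was 3.18 (3.21 to 3.26 with split controls), against a simulated 0.082. The least-squares slope of the iEC change on the HUVEC change, where 0 is CASMC and 1 is HUVEC, was 0.680 over 6 assignments of the CASMC libraries (0.661 to 0.695). It ran over 3808 to 4007 genes called HUVEC against CASMC with an absolute log2 fold change of at least 1. The slope does not describe genes off this line: 970 were called higher and 558 lower in iEC than in both CASMC and HUVEC. Single iEC libraries, taken on differences of log2 CPM and not on fitted fold changes, gave 0.723 ± 0.065 (SD, n = 4). The value was 0.820 in replicate 4 and 0.687 to 0.697 in the others, and these are not on the same measure as 0.680.

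**Figure D2:**
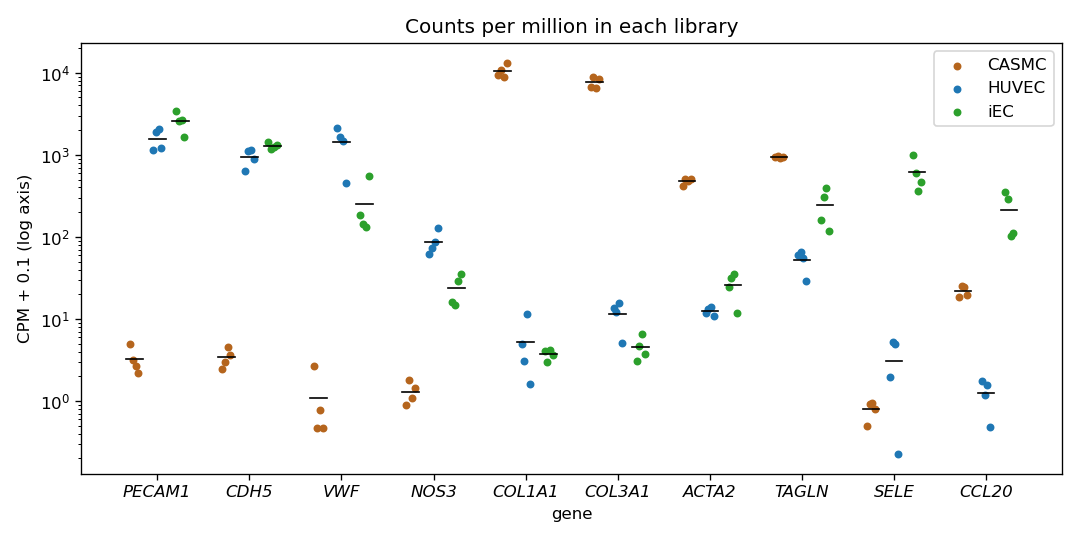
CPM of 10 genes in each library, with 0.1 added, on a log axis. Points are libraries and black lines are group means (n = 4 each). PECAM1 and CDH5 in iEC lie near HUVEC, COL1A1 and COL3A1 in iEC lie far below CASMC, and SELE and CCL20 lie above both other groups in all 4 iEC libraries.

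The comparison of iEC with HUVEC asks how iEC differed from the endothelial reference, both kept in endothelial medium. Cytokines and adhesion molecules of inflammation were higher in iEC. SELE, the endothelial selectin (chromosome 1, 169722641 to 169764705, minus strand, GRCh38), stood at 609 ± 282 CPM in iEC against 3.01 ± 2.43 in HUVEC. The chemokine CCL20 stood at 214 ± 126 against 1.14 ± 0.564 CPM, and the colony-stimulating factor CSF2 at 55.9 ± 40.9 against 0.126 ± 0.153 CPM (SD, n = 4 each). The log2 fold change of CSF2 was 8.97, and 9.85 without HUVEC replicate 1. Several endothelial effectors were lower: VWF at 252 ± 199 against 1430 ± 705 CPM, and NOS3 at 23.8 ± 9.93 against 87.7 ± 29.8 CPM. The groups overlapped for VWF: iEC replicate 4 had 548 CPM, against 133 to 184 in the other 3 iEC libraries and 454 in HUVEC replicate 4.

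In iEC 2510 genes were higher and 2011 lower than in HUVEC. Without iEC replicate 4 the counts were 2908 and 2573, and without iEC replicate 2 the lower count was 1236. Of 33 NF-kappaB inflammatory genes 32 were higher and 0 lower, with a median log2 fold change of 4.18 (the same counts adjusted over the list alone; camera adjusted p = 3.41e-46, and 0.0205 with an estimated correlation). Against CASMC, 16 of the 33 were higher in iEC and 7 lower (17 and 8 adjusted over the list alone). That list was not called (camera adjusted p = 0.207, and 0.760 with an estimated correlation), while 24 of 33 were lower in HUVEC than in CASMC. Of 35 interferon response genes 33 were higher and 0 lower (34 and 0 adjusted over the list alone; camera adjusted p = 6.19e-18, and p = 0.229 with an estimated correlation). TGF-beta responsive genes were higher in 13 of 30 cases and lower in 1 (14 and 1 adjusted over the list alone; camera adjusted p = 6.46e-09, and 0.0205 with an estimated correlation).

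Of the 44 endothelial surface genes, 8 were higher in iEC than in HUVEC and 11 lower (9 and 13 adjusted over the list alone; camera adjusted p = 0.449). VWF had a log2 fold change of -2.51 ± 0.58 (-3.22 without iEC replicate 4) and NOS3 -1.88 ± 0.31. PECAM1 (0.70 ± 0.27, adjusted p = 0.0662), CDH5 (0.45 ± 0.20, adjusted p = 0.112), KDR (0.51 ± 0.40, adjusted p = 0.363), TEK (0.52 ± 0.34, adjusted p = 0.266) and ERG (-0.17 ± 0.36, adjusted p = 0.759) did not pass the test. PECAM1 passed without iEC replicate 4 (adjusted p = 0.0158), HUVEC replicate 3 (0.0474) or CASMC replicate 1 (0.0463) and with the DESeq2 Wald test (0.0404), and over all alternatives its adjusted p ran from 0.0158 to 0.191. Endothelial transcription factors were lower in 12 of 27 cases and higher in 1 (12 and 2 adjusted over the list alone; camera adjusted p = 0.000239, and p = 0.210 with an estimated correlation). Smooth muscle genes were higher in 17 of 32 cases and lower in 2 (the same adjusted over the list alone; camera adjusted p = 0.00112, and p = 0.246 with an estimated correlation), with TAGLN at 2.23 ± 0.34 and ACTA2 at 1.04 ± 0.25. Without iEC replicate 3, 11 smooth muscle genes were higher. Matrix genes were higher in 13 of 34 cases and lower in 4 (15 and 4 adjusted over the list alone; camera adjusted p = 0.000951, p = 0.309 with an estimated correlation, and 0.0518 without HUVEC replicate 4).

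Sterol synthesis genes were lower in iEC than in HUVEC in 18 of 24 cases (the same adjusted over the list alone; camera adjusted p = 5.08e-07, and p = 0.246 with an estimated correlation). Angiogenic factors and receptors were higher in 11 of 33 cases and lower in 4 (13 and 4 adjusted over the list alone; camera adjusted p = 0.00251, and 0.0466 with an estimated correlation), and reported targets of miR-143-3p and miR-145-5p in 13 and 5 of 34 (15 and 5 adjusted over the list alone; camera adjusted p = 0.00237, and p = 0.210 with an estimated correlation). Cell cycle genes were lower in 26 of 40 cases (35 adjusted over the list alone and 17 with DESeq2; camera adjusted p = 4.55e-10, and p = 0.383 with an estimated correlation). That count was 5 without HUVEC replicate 4, whose mean over the list was 6.82 log2 CPM against 4.94 to 5.21 in the other 3 HUVEC libraries, and 39 without iEC replicate 4. The lowest single genes were METTL7A (-4.79 ± 0.68), the integrin ITGB4 (-4.42 ± 0.73), CLU (-3.65 ± 0.41) and KRT19 (-3.46 ± 0.58). METTL7A and KRT19 had -6.45 and -4.77 without iEC replicate 4, and ITGB4 -5.07 without iEC replicate 3. CLU stood at 428 CPM in HUVEC replicate 4 against 1639 to 1983 CPM in the other 3.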

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

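The tests of a mixed cell source, of admixed HUVEC RNA and of depth were chosen after the results they bear on were seen. In 348 groups of 4 libraries tested for a library far from the other 3, 24 were found, where chance gives about 17.4. Genes with reads in a single library of a group reach the highest value of this measure by construction. The tests also share libraries and genes, so the excess over 17.4 was not itself tested.

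iEC held PECAM1, CDH5 and KDR at HUVEC-like levels, and fibrillar collagens such as COL1A1 and COL3A1 far below CASMC. HUVEC RNA mixed into the iEC libraries would give at most the HUVEC level, but 8 endothelial surface genes were higher in iEC than in HUVEC, which argues against it as the whole cause. That count ran from 6 to 9 with 1 library left out. Among the 8, ENG lost its call in some of these settings, with an edgeR adjusted p of up to 0.0957. A candidate explanation, which the check for mixed-up samples goes with, is iEC of another cell source than the CASMC sequenced. None of the 4 iEC libraries matched the CASMC sequenced, at any of the 4 cutoffs. That count does not say whether another source was other CASMC or another kind of cell. Conversion by the 4 agents and the change of medium were not tested, since no library had one without the other.

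iEC replicate 4 lay nearer HUVEC than the other iEC libraries did. Its total of 26578667 counts lay within the range of theirs, which argues against depth. Genes high in HUVEC put its HUVEC share at a median of 0.42 (quartiles 0.17 and 0.55), and genes high in the other iEC libraries at 0.72 (0.47 and 0.88). Admixed HUVEC RNA would keep genes above the share of 0.42 of their lowest HUVEC level. Of 7833 genes, 19 fell below 0.5 of that bound, under the 78 to 135 of the other iEC libraries at the same bound. HUVEC libraries gave 0 to 163 against the other 3, but at 0.5 of the full level, which more genes can miss, so that range is not a like measure. A low count cannot tell admixture from expression nearer HUVEC, so admixture remains a candidate explanation. As its whole difference from the other iEC libraries, HUVEC RNA mixed into iEC replicate 4 would keep list means within the gene-wise range of the other 7 iEC and HUVEC libraries: 3 of 28 lay outside, hypoxia at 7.65, interferon at 6.45 and sterol genes at 4.75 log2 CPM against bounds of 6.96, 5.71 and 4.91, but HUVEC replicate 4 also had 3 outside, so this stays open, as does a culture state of its own, which was not tested.

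Transcripts with seed sites showed no shift outside the range of random 7-mers, with percentiles of 30.3 and 42.5 for the mimics of miR-146a-5p and miR-181b-5p and 82.8 and 90.3 for the inhibitors of miR-143-3p and miR-145-5p. The bounds fixed before these were seen were under 5 for action of a mimic and over 95 for an inhibitor. All 4 lay inside the bounds, and with 3′ UTRs of 500 to 3000 bases the percentiles were 91.7 and 30.7 for the mimics and 41.3 and 94.1 for the inhibitors, so whether the agents acted on these transcripts cannot be told apart from chance. The difference in cell state between iEC and CASMC, which the design confounds with the agents, keeps it open.

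For the number of genes called, 1 of the 35 splits of the 8 libraries, the real one, gave as many in each comparison. The real and highest other counts were 5719 and 0 for iEC against CASMC, 6671 and 0 for HUVEC against CASMC, and 4521 and 440 for iEC against HUVEC. A share of 1 of 35 is the smallest that this test can give. Splits that mix the groups put the group difference into the spread, which lowers their counts. The test bears on how these libraries were grouped, and not on cultures or donors. For the number of gene lists called, the real split gave 15 and the highest other 14 for iEC against CASMC, and 15 and 13 for HUVEC against CASMC. Only the real split, 1 of 35, gave as many, but other splits came within 1 or 2 lists. Whether the preset correlation of camera is too permissive for these data was not settled, so chance is not excluded for these counts. For iEC against HUVEC the real split gave 10 lists and the highest other 11, and 6 of 35 splits gave as many, so chance cannot be excluded for that number. The highest other counts of lists came from the 16 splits that keep 0.5 of the real group difference, while the 18 that keep 0 of it gave at most 5, 3 and 7 lists in the same order.

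There were 10 lists that differed between iEC and HUVEC by camera with the preset correlation, of which 3 (NF-kappaB, TGF-beta and angiogenic genes) did with an estimated correlation. Their median log2 fold changes of iEC against HUVEC were -0.69 for endothelial transcription factors, 0.59 for smooth muscle genes, 0.50 for matrix genes, 0.61 for angiogenic factors and 0.74 for TGF-beta responsive genes. The medians were 4.18 for NF-kappaB genes, 2.25 for interferon genes, -1.93 for cell cycle genes, -0.74 for sterol genes and 0.66 for reported targets of miR-143-3p and miR-145-5p.

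Several lists had 1 library apart, given as mean log2 CPM. HUVEC replicate 4 stood at 4.20 for venous genes against 4.85 to 4.90 in the other 3, at 1.75 for pericyte genes, at 1.52 for NF-kappaB genes, at 6.82 for cell cycle genes and at 3.90 for reported miR-146a-5p targets. iEC replicate 4 stood at 7.65 for hypoxia and glycolysis genes. CASMC replicate 1 stood at 3.87 for pericyte genes, and CASMC replicate 4 at 1.78 for Notch genes.

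Single genes with 1 library apart in iEC were KSR2 (103.0 CPM in replicate 3), TEK (119.6 CPM in replicate 4), LAPTM5 (165.2 CPM in replicate 4), CA12 (4.96 CPM in replicate 1) and GIMAP7 (11.7 CPM in replicate 2). In HUVEC they were FHL1 (45.7 CPM in replicate 3), MFNG (267.7 CPM in replicate 1), C15orf48 (0.375 CPM in replicate 2) and CLU (427.7 CPM in replicate 4). In CASMC they were CNN1 (20.8 CPM in replicate 2) and PID1 (89.6 CPM in replicate 1). Another 5 had reads in 1 library of the group alone: MERTK (0.0427 CPM) and CADM3 (0.0854 CPM) in CASMC replicate 3, ICA1 (0.101 CPM) in CASMC replicate 1, CPXM2 (0.0314 CPM) in HUVEC replicate 4 and GALNT5 (0.119 CPM) in HUVEC replicate 3.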

How the results depend on the processing

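All alternatives were fixed before the data were examined. Counts of genes called stayed within 1.5 times under other scalings, filters, DESeq2 and fits of 2 groups. With a log2 fold change of at least 1 they were 3714 for iEC against CASMC (1579 lower), 4381 for HUVEC against CASMC (2219 higher) and 2663 for iEC against HUVEC (1586 higher, 1077 lower), and 1138 genes were lower in both comparisons against CASMC. At an adjusted p under 0.01, 1651 were lower in iEC than in CASMC, and 2372 differed between iEC and HUVEC (1499 higher, 873 lower). These fall by construction. With 1 library left out, lower genes in iEC against HUVEC ranged from 1236 to 2573. With an estimated correlation 6, 6 and 3 lists were called for iEC against CASMC, HUVEC against CASMC and iEC against HUVEC, and fry called 23 and 20 for the last 2. With 3′ UTRs of 500 to 3000 bases the seed-site difference changed sign, uncalled in both settings, to 0.029 for miR-146a-5p and 0.039 for miR-145-5p in iEC against CASMC and 0.023 for miR-145-5p in HUVEC against CASMC; the cause was not tested.

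Lists uncalled in both settings that changed direction in at least 1 of these had the following adjusted p-values; the cause was not tested. Angiogenic factors in iEC against CASMC had 0.971 with the stricter filter and 0.775 to 0.982 with 1 library left out, and host genes 0.816 to 0.988. Leukocyte genes in HUVEC against CASMC had 0.751 to 0.998 with 1 library left out. Arterial genes in iEC against HUVEC had 0.595 with fry, 0.999 with the stricter filter and 0.660 to 0.999 with 1 library left out, and BMP genes 0.508 to 0.966. Of values for single genes under alternatives, 48 lost their call, 8 gained one and 1 changed sign. That was MIR181A2HG in iEC against CASMC, uncalled in both settings, at 0.17 without CASMC replicate 4 in a range of -0.47 to 0.17 with 1 library left out; the cause was not tested.

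Replicate numbers did not pair the libraries: correlations of deviations between same-numbered libraries ran from -0.06 to 0.22, 1 of 12 was over 0.1, and 0 of 12 libraries correlated best with their own number. With a replicate block, list directions changed, uncalled, for angiogenic factors in iEC against CASMC (adjusted p = 0.908), leukocyte genes in HUVEC against CASMC (0.901) and arterial genes in iEC against HUVEC (0.809). The list calls it added were cell cycle (0.00781) and BMP genes (0.0346) in iEC against CASMC. Without the block these lists had 0.824 and 0.354 with an estimated correlation. The slope of the iEC change, with all CASMC libraries in both comparisons, was 0.714 with the block and 0.710 without. Depth limits values under the floors of 0.0893 to 0.171 CPM. At the depth, spread and group size of these libraries, which were not varied, the simulation recovered 1.14% of changes of 0.5 on the log2 scale in iEC against CASMC.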

Other observations

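HOX genes, which keep a record of position along the body axis, were looked at after their values were seen. Of 21 measured, 9 were higher and 5 lower in iEC than in CASMC, and 1 was higher and 3 lower in iEC than in HUVEC. HOXA9 stood at 34.2 ± 6.87 CPM in iEC, 44.1 ± 3.91 in HUVEC and 0.494 ± 0.478 in CASMC (SD, n = 4 each). HOXA10 stood at 14.1 ± 0.959, 19.9 ± 2.11 and 2.28 ± 1.30 CPM. HOXA5 was the other way, at 7.91 ± 1.80 CPM in iEC, 13.6 ± 4.74 in HUVEC and 24.3 ± 4.70 in CASMC. Whether these differences go with cell type, cell source or conversion was not tested.

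Other lists of iEC against CASMC were called higher for Notch signalling (13 of 22 genes higher, 3 lower), lymphatic endothelial genes (8 of 10, 0 lower), arterial (14 of 21, 5 lower) and venous endothelial genes (9 of 13, 2 lower) and p53 targets (12 of 24, 2 lower). Lists called lower were mesenchymal transition factors (7 of 14 lower, 3 higher), osteochondrogenic genes (3 of 9, 1 higher) and the unfolded protein and stress response (14 of 29, 3 higher). Adjusted over the list alone the counts were 10 higher for venous, 14 higher for p53, 15 lower for stress response and 4 higher for mesenchymal transition genes, and otherwise the same. Of these, Notch, lymphatic and mesenchymal transition lists held with an estimated correlation (adjusted p = 0.0153, 0.0147 and 0.0164), and the others had an adjusted p of 0.0584 for arterial and venous, 0.118 for p53, 0.0599 for osteochondrogenic and 0.0904 for stress response genes. Lists of pericyte (adjusted p = 0.330), leukocyte (0.453), epithelial (0.0689), pluripotency (0.837), TGF-beta (0.184), BMP (0.0523), angiogenic (0.986), NF-kappaB (0.207), cell cycle (0.0826) and microRNA host genes (0.986) were not called. BMP genes passed without HUVEC replicate 3 (0.0482), iEC replicate 1 (0.0311) or iEC replicate 2 (0.0374) and with DESeq2 size factors (0.0488), epithelial genes without iEC replicate 1 (0.0418) or iEC replicate 2 (0.0384), and cell cycle genes without iEC replicate 4 (0.000204). With an estimated correlation and all libraries these 3 lists had 0.354, 0.264 and 0.824. Medians were negative while means and test were positive for leukocyte, epithelial and angiogenic genes. For pericyte genes the median and mean were negative (-3.88 and -0.67) and the test positive.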
